A study of Mus musculus with 4 samples.

How the data were processed

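RNA sequencing libraries had been made from CD4+Foxp3+ Treg cells of spleen and peripheral lymph nodes of C57BL/6 mice, with 2 libraries labelled WT and 2 labelled P65KO. Per the labels' protocols, RNA was purified with an RNeasy Plus Mini kit and libraries were prepared with an Illumina TruSeq RNA kit. Per the submitters' processing notes, Subread, featureCounts and limma were used and the genome build was GRCm38 (mm10). Their versions, the role of limma, the annotation and the strand setting of the counting are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. No label says that replicates came from separate mice, so p-values of single genes measure only the spread between these 4 libraries, which may be partly technical. The list p-values at a preset correlation weigh the genes of a list against the other genes. They are not a measure of the spread between libraries.

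The authors deposited raw counts per Entrez gene for the 4 libraries in a table of 27179 genes, of which 571 carried no symbol. They also deposited a log2 RPKM value per gene for each library. The deposited log2 RPKM values equalled the log2 of the count plus 0.5, divided by the gene length and the total count of the library, with no scaling between libraries. Computed back from these values, the gene length was a whole number within 0.01 for 27178 genes, and the 4 libraries gave 1 length within 0.01 for 27179 genes. The log2 RPKM values therefore hold the same counts, and tests were run on the counts as deposited. Genes without a symbol held 0.453% to 0.562% of the counts and were kept, since each has an Entrez identifier.

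Coordinates came from a RefSeq gene table of the assembly GRCm38.p6, the same build, matched on the Entrez identifier for 25275 genes of the table and for 11008 of the 11172 genes tested. Reads from near-identical genes cannot be assigned with certainty. Ribosomal protein genes have processed pseudogenes that may share their reads, which was not tested, so their values are uncertain, as are those of the Bcl2a1 and globin copies and of immunoglobulin segments. Overlapping and antisense genes are likewise uncertain, since the strand setting is not known.

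Library totals ran from 4513863 to 4624230 counts. A floor of 3 counts corresponded to 0.646 to 0.664 CPM in a single library. Folds against a group with 0 counts in both libraries were computed against 3 counts over the group and are lower bounds. For genes with 1 to 3 counts over a group, the ratio is given with an exact 95% conditional binomial interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

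Genes with low counts were removed with filterByExpr, library sizes were scaled by TMM, and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is said to have risen or fallen only where it passed that threshold. CPM values are scaled by TMM. The standard error of a log2 fold change was its size divided by the square root of F. Before the data were examined, the tests, the naming rule, 27 gene lists and the other settings to be tried were fixed. The script was tested on simulated counts for 11172 genes with 200 genes changed, and it called 56.7% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 95.5% of those changed 4-fold. Of its 152 calls, 1 was false. With no change simulated, it called 0 genes and 0 of 25 lists. The simulated genes varied independently, so this does not show how the list test behaves where the genes of a list vary together. The 200 changed genes were also far fewer than the 2310 called in the data. Each simulated gene varied just as the trend over expression gives, with no spread of single genes around that trend. The share of false calls in the data may therefore be higher.

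The lists, matched by exact symbol, were NF-kB family and inhibitors, textbook NF-kB target genes, TNF receptor superfamily, TNF superfamily ligands and TRAF adaptors, effector Treg markers, naive and central Treg or T cell markers, core Treg identity genes, T helper lineage regulators and cytokines, apoptosis regulators, chemokine receptors and trafficking molecules, cell cycle genes, interferon-stimulated genes, MHC class I and antigen processing, T cell activation early response genes, heat shock and stress genes, glycolysis genes, cholesterol synthesis genes, ribosomal protein genes, oxidative phosphorylation genes and sex-linked genes. Markers of other cell types were listed for B cells, CD8 T cells, NK and innate lymphoid cells, gamma-delta T cells, myeloid and dendritic cells, erythroid cells and platelets, and stromal and endothelial cells. Of 584 symbols, 3 were absent from the table. Lists share members, such as the 20 effector markers that stand in another list too. Lists with at least 3 tested genes were compared with the other genes by camera of limma 3.58.1, with the correlation between genes preset at 0.01. The adjustment ran over 25 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were alternatives. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries. That leaves little power after adjustment, whatever the correlation.

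Named genes were Rela, then the 10 highest and the 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. Predicted genes, pseudogenes, sex-linked genes and receptor segments were left out of those 20, which removed 73 higher and 49 lower genes from 2008. From each list, the members with the smallest adjusted p were named, up to 8 for the TNF receptor, NF-kB and effector lists and up to 4 for the others. Members named only to spell out a count of 5 or fewer were chosen after their values were seen. Results for some genes that the rule names are not reported here.

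The other settings tried were RLE and upper-quartile scaling, no filter, a stricter filter of at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes estimation, a replicate block and each library left out in turn. Leaving X and Y genes out, removing a trend with gene length, and a crossed block were added after the data were seen. Counts of the single-library files were not tested separately, because those files hold log2 RPKM of the same counts.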

Results

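Transcriptomes were measured by RNA sequencing in CD4+Foxp3+ regulatory T cells (Treg cells), the T cell subset that restrains immune responses, taken from spleen and peripheral lymph nodes of C57BL/6 mice at steady state. There were 2 WT libraries and 2 libraries labelled P65KO, described as RelA-deficient. RelA (p65) is a DNA-binding subunit of the NF-kB transcription factors. The WT libraries held 4513863 and 4612500 counts, and the P65KO-labelled libraries 4598244 and 4624230, with 14025 to 14392 genes detected in each. The correlation of log2 CPM across genes was at least 0.982 within a group and at most 0.936 between groups, while replicates still differed by more than counting noise (chi-square per degree of freedom 3.65 in WT and 4.14 in P65KO-labelled). The labels pose the question of how Treg expression depends on RelA, with the TNF receptor superfamily and the effector Treg program in focus. These 4 libraries could not separate the genotype label from the sex-linked difference described below.

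Rela itself did not fall at the level of the whole gene. Effector Treg genes were lower in the P65KO-labelled libraries: 45 of 49 tested markers fell, among them the inhibitory receptor genes Tigit, 35.7-fold lower, and Klrg1, 42.2-fold lower. Markers of naive and central cells went the other way, and 22 of 27 rose, including the chromatin organiser gene Satb1, which was 2.52-fold higher. The TNF receptor genes Tnfrsf1b (TNFR2), Tnfrsf9 (4-1BB) and Tnfrsf4 (OX40) fell 2.57-fold, 2.36-fold and 2.15-fold. Foxp3, the lineage-defining factor, stood at 374 ± 4.25 CPM in WT and 457 ± 100 CPM in P65KO-labelled libraries (SD, n = 2 each) and did not pass the test.

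Rela (Entrez 19697; GRCm38 chromosome 19, 5637442 to 5648134) had 875 and 806 counts in the WT libraries and 820 and 909 in the P65KO-labelled libraries. Its expression was 182 ± 11.6 CPM in WT and 191 ± 14.5 CPM in P65KO-labelled libraries (SD, n = 2 each), a log2 difference of 0.07 (SE 0.10; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.662). The 95% interval, -0.14 to 0.28, corresponds to 0.908-fold to 1.22-fold. Without P65KO-labelled replicate 2 the log2 difference was -0.01. Counts over a whole gene include exons outside a deleted part, so they could not check the genotype label, and directions are given for the libraries as labelled.

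The groups also differed in sex-linked genes. Xist, the noncoding RNA of X inactivation, had 494 and 608 counts in WT and 0 and 2 in P65KO-labelled libraries, a ratio of 539 (exact 95% interval 149 to 4455). Its fitted log2 difference of -8.91 was -7.98 without P65KO-labelled replicate 1 and -12.10 without P65KO-labelled replicate 2. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 counts in both WT libraries and were at least 241-fold, 260-fold and 149-fold higher in P65KO-labelled libraries, and Uty was 38.6-fold higher (interval 18.5 to 96.9). All 5 sex-linked genes passed the test over all genes, 4 higher and 1 lower, and the same numbers adjusted over the list alone. The list median was 10.79 on the log2 scale, or 7.22 with the genes at 0 counts set to their bound (camera, Benjamini-Hochberg adjusted p = 1.15e-13). That call was lost at adjusted p = 0.111 with an estimated correlation. Genotype label and these sex-linked signals changed together in all 4 libraries, so each difference reported here is also a difference between libraries with Xist and libraries with Y-linked transcripts. Myeloid markers (11 of 16) and erythroid markers (4 of 4 tested) rose in the P65KO-labelled libraries too. Every list reported here was therefore compared between libraries that also differed in these transcripts.

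Of 11172 genes tested, 2310 (20.7%) passed the threshold, with 1005 higher and 1305 lower in P65KO-labelled libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 328 were more than 2-fold higher and 628 more than 2-fold lower. Without the genes of the X and Y chromosomes, 969 rose and 1261 fell. The number of changed genes was 771 with no filter on low counts (246 higher, 525 lower), 1318 with DESeq2, 919 without WT replicate 1 and 916 without WT replicate 2.

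**Figure D1:**
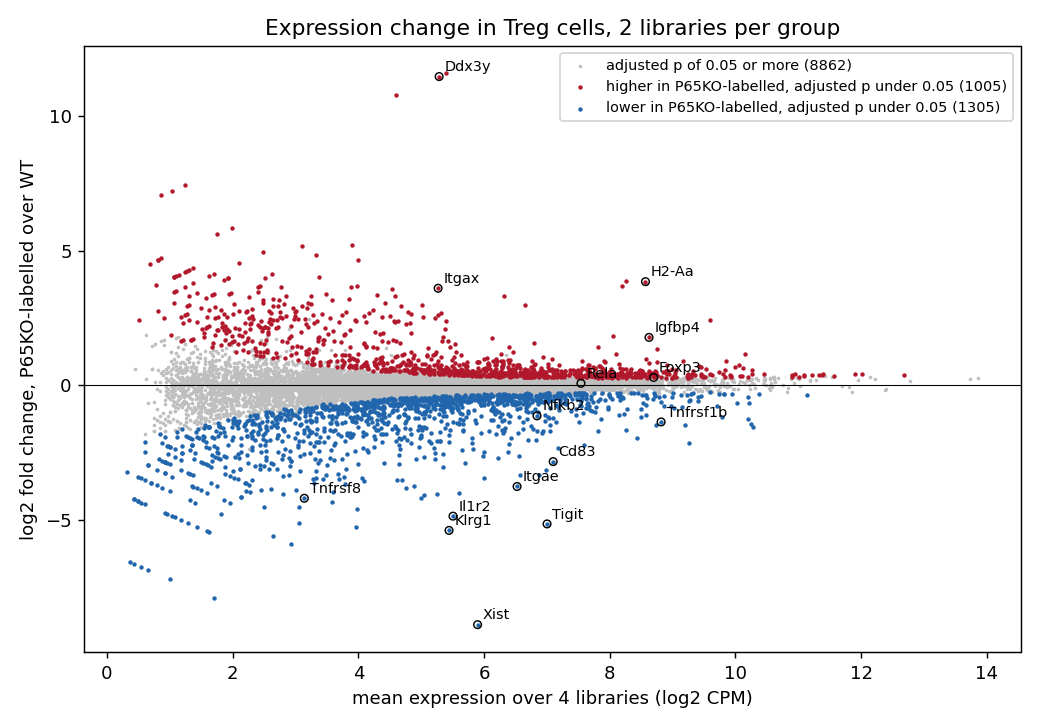
Mean expression over the 4 libraries (log2 CPM, horizontal axis) against the log2 fold change of P65KO-labelled over WT libraries (vertical axis), 1 point per tested gene, with 1005 higher genes in red, 1305 lower genes in blue and the others in grey. Circled genes are named, with Rela near 0 (0.07), Tigit and Klrg1 far below 0 (-5.16 and -5.40) and H2-Aa far above (3.85).

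The 10 lowest genes by the naming rule included several surface molecules. Tigit (Entrez 100043314; GRCm38 chromosome 16, 43626137 to 43665125) fell from 250 ± 10.5 to 6.96 ± 2.36 CPM (SD, n = 2 each; log2 -5.16, SE 0.16; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.60e-09). Klrg1 (Entrez 50928; chromosome 6, 122270596 to 122282833) fell from 85.0 ± 3.31 to 1.99 ± 0.619 CPM (log2 -5.40, SE 0.20; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.46e-09). Il1r2, the decoy receptor for interleukin-1, was 29.2-fold lower, and Sostdc1, a secreted antagonist of BMP and Wnt signalling, was 24.5-fold lower. Ces2c, a carboxylesterase, fell 38.2-fold, Serpina3f, a serine protease inhibitor, 34.6-fold and Sccpdh 20.3-fold. The JNK scaffold gene Mapk8ip1 fell by log2 -4.54, or -3.58 without P65KO-labelled replicate 1 and -8.65 without P65KO-labelled replicate 2, with 0 and 4 counts in those libraries. Arnt2, a bHLH-PAS transcription factor, had 139 counts in WT and 2 in P65KO-labelled libraries, a ratio of 68.0 (exact 95% interval 18.5 to 567), and Slc7a10, an amino acid transporter, had 113 and 2, a ratio of 55.3 (14.9 to 462). Both counts of each gene lay in P65KO-labelled replicate 1. The fitted log2 differences of Arnt2 and Slc7a10, -5.92 and -5.62, were -9.11 and -8.81 without that library and -5.01 and -4.71 without P65KO-labelled replicate 2.

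The effector Treg list fell as a group. Over all genes tested, 45 of its 49 members were lower, 1 was higher and 3 did not pass, against 45 lower and 2 higher adjusted over the list alone. The median log2 fold change was -1.70 (camera, Benjamini-Hochberg adjusted p = 1.51e-82). The call was lost at adjusted p = 0.104 with an estimated correlation. The transcription factor gene Maf fell from 173 ± 19.1 to 17.2 ± 0.988 CPM (SD, n = 2 each). The integrin gene Itgae (CD103) fell 13.6-fold, the chemokine receptor gene Cxcr3 8.83-fold, and the inhibitory receptor genes Lag3 and Pdcd1 (PD-1) 6.15-fold and 5.02-fold. Icos, a costimulatory receptor that supports effector Treg cells, fell 4.70-fold, from 319 ± 32.6 to 67.9 ± 6.21 CPM. Havcr2 (Tim-3), the member that rose, was 2.38-fold higher at low expression, a call that ended without WT replicate 1, WT replicate 2 or P65KO-labelled replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.174, 0.264 and 0.265). It also ended with no filter (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.169), with DESeq2 (Benjamini-Hochberg adjusted p = 0.189) and with limma-voom (0.0635). Selp, Lgals3 and Ikzf3 did not pass. Areg (amphiregulin) had 0 counts in both P65KO-labelled libraries, at least 7.82-fold lower, and the median remained -1.70 with Areg at that bound. The call of Areg ended with no filter and without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0622 and 0.0560). The libraries with fewer effector transcripts were also those with Y-linked transcripts and with more myeloid transcripts, for example Itgax at 71.3 against 5.83 CPM.

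Naive and central markers rose as a group. Of 27 members, 22 were higher, 2 lower and 3 did not pass, with the same 22 and 2 adjusted over the list alone, and the median was 0.90 (camera, Benjamini-Hochberg adjusted p = 3.74e-23). It was lost at adjusted p = 0.154 with an estimated correlation. Igfbp4, a binding protein of insulin-like growth factors, rose 3.43-fold, from 178 ± 1.98 to 612 ± 24.4 CPM (SD, n = 2 each). Ly6c1, a GPI-anchored surface antigen, rose from 55.3 to 166 CPM, and Satb1 rose 2.52-fold, from 245 ± 10.7 to 617 ± 70.4 CPM. Il7r, the interleukin-7 receptor, fell 1.89-fold, and Art2b, an ADP-ribosyltransferase, fell 1.56-fold, a call that ended with no filter and without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0904 and 0.0558). The libraries with more of these naive markers were also those with Y-linked transcripts (Ddx3y at 66.6 and 89.5 CPM against 0 counts in WT) and with more myeloid transcripts, such as Adgre1 at 35.9 against 3.45 CPM.

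Among core Treg identity genes, 13 of 25 fell, 5 rose and 7 did not pass, with the same 13 and 5 adjusted over the list alone. Their median was -0.33 (camera, Benjamini-Hochberg adjusted p = 1.63e-07), and the call was lost at adjusted p = 0.364 with an estimated correlation. Penk, which encodes proenkephalin, fell 10.9-fold, the semaphorin and VEGF co-receptor gene Nrp1 3.89-fold and Ikzf2 (Helios) 3.14-fold. Gpr83, Ecm1, Cbfb, Il2ra (CD25) and Socs2 rose, Il2ra by 1.34-fold. With no filter on low counts, the calls of Ecm1, Cbfb, Il2ra and Socs2 ended (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0697, 0.0541, 0.114 and 0.209), and Il2ra and Socs2 also lost theirs without WT replicate 1, WT replicate 2 or P65KO-labelled replicate 2. Ecm1 did so without WT replicate 2, Cbfb without WT replicate 1 or P65KO-labelled replicate 2, and Socs2 with DESeq2 (Benjamini-Hochberg adjusted p = 0.244) and limma-voom (0.0613). Foxp3 (log2 0.29, SE 0.13; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.131) had an unadjusted 95% interval of 0.02 to 0.56.

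The NF-kB system was lower in most of its called members. In the list of NF-kB family members and inhibitors, 10 of 18 genes fell, 1 rose and 7, Rela among them, did not pass, with the same 10 and 1 adjusted over the list alone. The median was -0.36 (camera, Benjamini-Hochberg adjusted p = 4.97e-05), lost at adjusted p = 0.364 with an estimated correlation. Tnfaip3 (A20), a ubiquitin-editing inhibitor of NF-kB, fell 2.57-fold, from 121 ± 1.04 to 47.1 ± 2.32 CPM (SD, n = 2 each). The non-canonical subunit genes Nfkb2 and Relb fell 2.20-fold and 2.02-fold, and Nfkbia, the inhibitor IkB-alpha, 1.98-fold. Nfkbid and Bcl3, nuclear IkB proteins, fell 1.82-fold and 1.55-fold. Rel (c-Rel) fell 1.52-fold, a call that ended with no filter, with DESeq2 and without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.112). Map3k14, the NF-kB inducing kinase of the non-canonical pathway, rose 1.73-fold.

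Textbook NF-kB target genes shared 32 of their members with other lists, and 25 of 38 tested fell, 3 rose and 10 did not pass, against 26 and 4 adjusted over the list alone. The median was -0.51 (camera, Benjamini-Hochberg adjusted p = 1.66e-13), lost at adjusted p = 0.104 with an estimated correlation. Cd83, an activation marker, fell 7.16-fold, from 241 ± 15.5 to 33.6 ± 5.53 CPM (SD, n = 2 each). Ebi3, a subunit of interleukin-35 and interleukin-27, fell 6.73-fold, the effector transcription factor gene Irf4 2.51-fold and the adhesion molecule gene Icam1 2.43-fold. The members that rose were Ccr7, a homing receptor of naive and central cells that was 1.89-fold higher, Myc, 1.45-fold, and Il2ra. The call of Myc ended with no filter and without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0714 and 0.0809).

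In the TNF receptor superfamily, 7 of 17 genes fell, 2 rose and 8 did not pass, with the same 7 and 2 adjusted over the list alone. The median was -0.40 (camera, Benjamini-Hochberg adjusted p = 5.23e-04). The call was lost at adjusted p = 0.196 with an estimated correlation, and at 0.260 with no filter on low counts. Tnfrsf1b (Entrez 21938; GRCm38 chromosome 4, 145212368 to 145246870) fell from 650 ± 27.0 to 252 ± 0.830 CPM (SD, n = 2 each; log2 -1.36, SE 0.09; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.19e-07). Tnfrsf9 fell from 328 ± 24.0 to 139 ± 15.6 CPM and Tnfrsf4 from 389 ± 6.66 to 181 ± 6.46 CPM, and Tnfrsf8 (CD30) fell from 16.8 ± 5.45 CPM by log2 -4.20, or -6.08 without P65KO-labelled replicate 1 and -3.42 without P65KO-labelled replicate 2. Tnfrsf18 (GITR) was 1.38-fold lower and Tnfrsf14 (HVEM) 1.43-fold lower. Tnfrsf1a (TNFR1) and Tnfrsf21 (DR6) were 1.39-fold and 4.44-fold higher, the latter from 1.30 to 5.85 CPM in the libraries that also held more myeloid transcripts. Without P65KO-labelled replicate 1 the log2 difference of Tnfrsf21 was 1.34 and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.138). The calls of these last 4 genes ended with no filter and without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0735 for Tnfrsf18 and 0.202 for Tnfrsf14 without that library), and also without P65KO-labelled replicate 1. Those of Tnfrsf14, Tnfrsf1a and Tnfrsf21 ended without WT replicate 1 and with DESeq2 as well (DESeq2, Benjamini-Hochberg adjusted p of 0.327, 0.101 and 0.0599). Without P65KO-labelled replicate 2 the call of Tnfrsf14 ended too, at log2 -0.53. Cd27, a costimulatory receptor of the family, stood at 360 ± 27.7 and 359 ± 28.1 CPM.

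TNF superfamily ligands and TRAF adaptors had 8 of 19 genes lower, 1 higher and 10 that did not pass, against 11 and 3 adjusted over the list alone. Their median was -0.42 (camera, Benjamini-Hochberg adjusted p = 0.00448), lost at adjusted p = 0.232 with an estimated correlation. Tnfsf11 (RANKL), the ligand that drives osteoclast formation, fell 2.65-fold, and Tnfsf14 (LIGHT) 3.44-fold, the latter at log2 -2.38 without P65KO-labelled replicate 1 and not past the threshold with no filter (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0507). Traf4 was the gene that rose, a call that ended with no filter, with DESeq2 (Benjamini-Hochberg adjusted p = 0.129) and without WT replicate 1, WT replicate 2 or P65KO-labelled replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.130, 0.0600 and 0.0615).

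**Figure D2:**
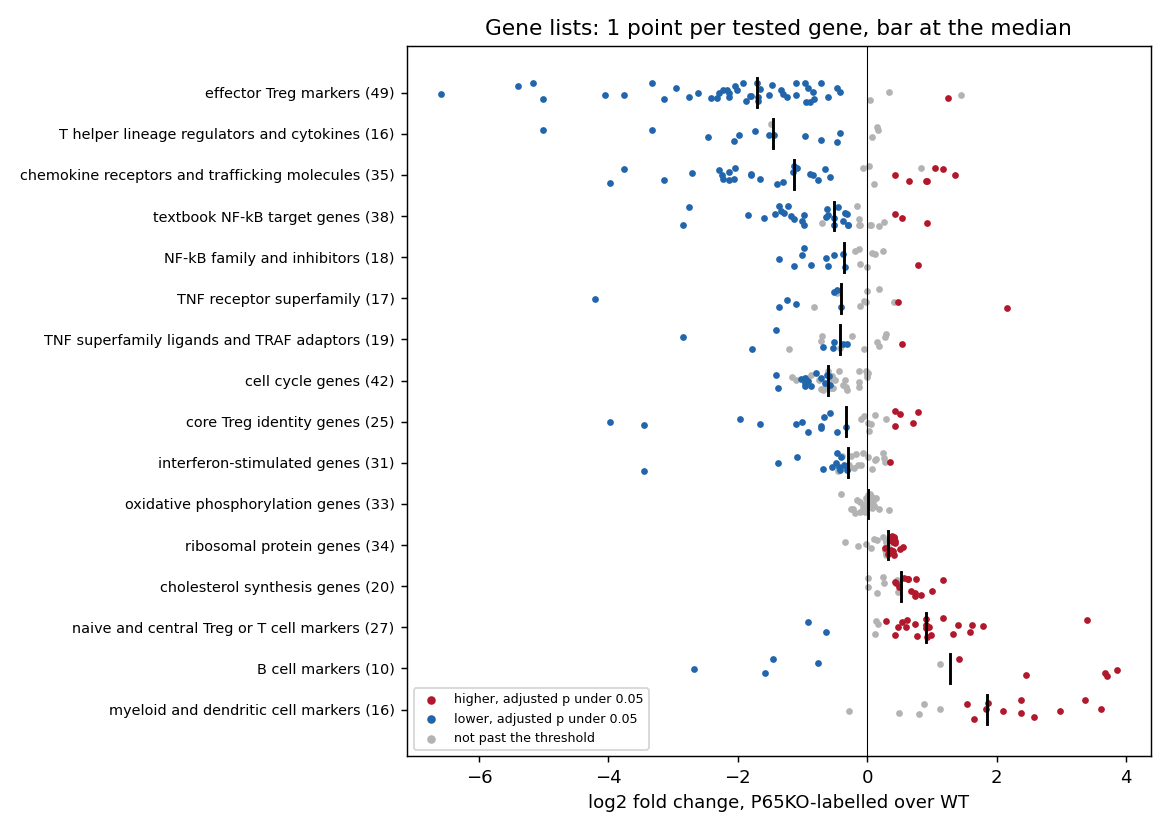
Log2 fold change of P65KO-labelled over WT libraries (horizontal axis) for each tested member of 16 gene lists (vertical axis, number of tested genes in brackets), with members past the threshold in red (higher) or blue (lower) and a bar at the list median. Effector Treg markers lie to the left (median -1.70), and myeloid and dendritic markers to the right (median 1.85). The erythroid and sex-linked lists are among those not drawn.

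Most genes of trafficking and of T helper lineages also fell. Of 35 chemokine receptor and trafficking genes, 24 fell, 7 rose and 4 (S1pr4, Ccr1, Itgb2 and Itgb7) did not pass, with the same 24 and 7 adjusted over the list alone. Myeloid markers rose in the same libraries (11 of 16, median 1.85). The median was -1.13 (camera, Benjamini-Hochberg adjusted p = 1.04e-14), lost at adjusted p = 0.104 with an estimated correlation. Ccr4, a receptor for skin and tissue homing, fell 6.52-fold and the integrin chain gene Itgb1 4.38-fold. Of 16 T helper lineage genes, 12 fell and 4 (Ifng, Stat6, Tgfb1 and Stat3) did not pass, against 13 lower adjusted over the list alone. The median was -1.46 (camera, Benjamini-Hochberg adjusted p = 7.66e-14), lost at adjusted p = 0.111 with an estimated correlation. Cxcr5, the follicle homing receptor, fell 4.15-fold, from 184 ± 26.3 to 44.2 ± 4.56 CPM (SD, n = 2 each). Ahr, the aryl hydrocarbon receptor, fell 3.94-fold, and Il12rb1, a receptor chain for interleukins 12 and 23, 2.71-fold.

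Some proliferation and interferon genes fell. Of 42 cell cycle genes, 14 fell and 28 did not pass, against 18 lower adjusted over the list alone, with a median of -0.60 (camera, Benjamini-Hochberg adjusted p = 4.47e-05). This was lost at adjusted p = 0.597 with an estimated correlation. The replication licensing gene Mcm6 fell 1.57-fold. Top2a, Melk and Mki67, the gene of the Ki-67 antigen, were 1.88-fold, 2.60-fold and 1.96-fold lower, calls that ended without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0796, 0.0631 and 0.110). Those of Top2a and Mki67 also ended without WT replicate 1 and with no filter (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0896 and 0.111 with no filter). Of 31 interferon-stimulated genes, 12 fell, 1 (Ifit2) rose and 18 did not pass, against 14 and 1 adjusted over the list alone. The median was -0.30 (camera, Benjamini-Hochberg adjusted p = 0.00448), lost at adjusted p = 0.581 with an estimated correlation. Cxcl10, a ligand of Cxcr3, fell 10.9-fold, the RNA sensor gene Ifih1 (MDA5) 1.61-fold and Oas1a, an oligoadenylate synthetase, 2.60-fold. The call of Ifit2 ended with no filter, with DESeq2 and without any 1 of the 4 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.146 for the latter).

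Most cholesterol synthesis genes rose. Of 20 members, 13 were higher and 7 did not pass, against 16 higher adjusted over the list alone, and the median was 0.53 (camera, Benjamini-Hochberg adjusted p = 1.27e-07). The call was lost at adjusted p = 0.111 with an estimated correlation. The synthesis enzyme gene Sqle rose 1.78-fold, from 33.4 ± 4.33 to 59.4 ± 1.42 CPM (SD, n = 2 each), and Cyp51 rose 1.55-fold. These libraries also held more myeloid and erythroid transcripts. Ribosomal protein genes, whose reads pseudogenes may share, were 17 higher of 34 with 17 not passing, against 25 higher adjusted over the list alone. Their median was 0.32 (camera, Benjamini-Hochberg adjusted p = 3.70e-06), lost at adjusted p = 0.581 with an estimated correlation. Rps7 was 1.47-fold higher and Rpl8 1.34-fold higher, calls that ended with no filter and without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0797 and 0.0959 without that library). That of Rpl8 also ended without either P65KO-labelled library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.0967).

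The remaining lists of cell function did not pass as groups. Of 28 apoptosis regulators, 6 fell, 2 rose and 20 did not pass, against 8 and 4 adjusted over the list alone (median -0.16; camera, Benjamini-Hochberg adjusted p = 0.358). Bcl2, the survival factor, rose 1.87-fold and Casp8 rose, while the survival gene Bcl2a1b fell 2.27-fold. Of 18 genes of MHC class I and antigen processing, 3 (Psme2, Tap1 and Tapbp) were lower and 15 did not pass, with the same 3 adjusted over the list alone (median -0.12; camera, Benjamini-Hochberg adjusted p = 0.198, or 0.00531 with no filter). The calls of these 3 genes ended with no filter and without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.103, 0.122 and 0.167 without that library). That of Psme2 also ended with DESeq2 (Benjamini-Hochberg adjusted p = 0.0671), and those of Tap1 and Tapbp with the replicate block and without any of the other 3 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.204 and 0.169). Of 24 early response genes, 8 fell, 3 (Jun, Myc and Klf6) rose and 13 did not pass, against 8 and 4 adjusted over the list alone (median -0.12; camera, Benjamini-Hochberg adjusted p = 0.180, or 0.0289 without WT replicate 2). Jun rose 3.23-fold, while Egr2, a factor induced by T cell receptor signals, fell 2.43-fold, Junb 1.96-fold and Nfatc1 1.82-fold. The call of Klf6 ended with no filter, with DESeq2, with the replicate block and without any 1 of the 4 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of up to 0.213 for the latter).

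Heat shock and stress genes had 3 of 17 higher (Dnaja1, Dnajb1 and Hsph1), 2 lower (Hspa5 and Asns) and 12 that did not pass, against 4 and 3 adjusted over the list alone (median 0.20; camera, Benjamini-Hochberg adjusted p = 0.477). The calls of Dnaja1, Dnajb1, Hsph1 and Asns ended with no filter and without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0621, 0.151, 0.216 and 0.0581 without that library), and those of the first 3 also without WT replicate 1 or P65KO-labelled replicate 1. Hsph1 also lost its call with DESeq2 (Benjamini-Hochberg adjusted p = 0.199) and Dnajb1 with robust estimation (edgeR quasi-likelihood, 0.0535). Glycolysis genes had 2 of 19 higher (Pdk1 and Eno1), 3 lower (Tpi1, Aldoa and Pgam1) and 14 that did not pass, with the same numbers adjusted over the list alone (median -0.07; camera, Benjamini-Hochberg adjusted p = 0.732). The calls of Eno1, Aldoa and Pgam1 ended with no filter and without WT replicate 1, WT replicate 2 or P65KO-labelled replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0799, 0.168 and 0.164 without the last), and that of Pgam1 also without P65KO-labelled replicate 1 and with DESeq2 (Benjamini-Hochberg adjusted p = 0.298). Oxidative phosphorylation genes had 0 of 33 past the threshold, also adjusted over the list alone, and 0 with DESeq2 and with limma-voom. At an unadjusted edgeR p under 0.05 there were 2. Uqcrfs1 passed with robust estimation, with either replicate block, without WT replicate 2 and with the length trend removed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0120 to 0.0391). Their median was 0.01 and their mean -0.01, of opposite sign (camera, Benjamini-Hochberg adjusted p = 0.732).

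Markers of other cell types were measured alongside. Myeloid and dendritic markers were higher in P65KO-labelled libraries for 11 of 16 genes, with 5 not passing and the same 11 adjusted over the list alone. Their median was 1.85 (camera, Benjamini-Hochberg adjusted p = 2.58e-09), lost at adjusted p = 0.410 with an estimated correlation. Itgax (CD11c), an integrin of dendritic cells, was 12.2-fold higher, at 94.2 and 48.5 CPM in P65KO-labelled replicates 1 and 2 against 4.12 and 7.53 CPM in WT. Adgre1 (F4/80) was 10.3-fold and Spi1 (PU.1), the myeloid transcription factor, 5.95-fold higher. Lyz2 (lysozyme) stood at 635 and 193 CPM in P65KO-labelled replicates 1 and 2 and at 90.9 and 141 CPM in WT. The call of Lyz2 ended with no filter, with DESeq2, with robust estimation and without either WT library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.342 with robust estimation), and its log2 difference of 1.84 became 0.74 without P65KO-labelled replicate 1 and 2.45 without P65KO-labelled replicate 2. The call of Tyrobp, another member that rose, ended with no filter, with robust estimation and without either WT library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.221 with robust estimation).

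The 10 highest genes by the naming rule included the MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and H2-Eb2, which present antigen on dendritic cells and B cells. H2-Aa (Entrez 14960; GRCm38 chromosome 17, 34282744 to 34287823) rose from 34.7 and 63.5 CPM in WT to 934 and 487 CPM in P65KO-labelled replicates 1 and 2 (log2 3.85, SE 0.30; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.13e-06). H2-Eb1 was 14.6-fold and H2-Eb2 25.4-fold higher, and H2-Ab1 rose from 42.0 to 546 CPM. Anpep (CD13), a membrane aminopeptidase, rose by log2 5.18 to 16.7 CPM (6.11 without WT replicate 1), and Apol7c by log2 4.85 to 19.4 CPM (3.89 without P65KO-labelled replicate 1). Adam23 was 17.4-fold higher at 11.7 CPM and Tbc1d9 16.1-fold higher. Mreg rose by log2 4.01 (3.30 without WT replicate 1 and 5.48 without WT replicate 2), and Fut4, a fucosyltransferase, by 3.69 (4.45 without WT replicate 2). With robust empirical Bayes estimation, the calls of H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Itgax ended (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0818, 0.0792, 0.0842, 0.0774 and 0.0713), and that of Apol7c ended with no filter (0.0561). Of the 110 genes that rose more than 4-fold at a mean of at least 5 CPM, 88 were over 1.5-fold higher in P65KO-labelled replicate 1 than in replicate 2. That held for 9 of the 11 called myeloid markers and for 197 of all 1005 genes that rose. The 110 lie within the 1005 and include myeloid markers such as Itgax, so these sets are not independent. Mreg differed less between those replicates, at 12.3 and 9.30 CPM.

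B cell markers had 5 of 10 genes higher, 4 lower and 1 (Jchain) that did not pass, against 6 and 4 adjusted over the list alone, with a median of 1.27 (camera, Benjamini-Hochberg adjusted p = 0.00660). The call was lost at adjusted p = 0.594 with an estimated correlation, at 0.381 with no filter and at 0.0813 without WT replicate 1. The higher members were H2-Aa, H2-Ab1 and the invariant chain Cd74, which dendritic cells express too, and the light chain genes Igkc and Iglc2. Lower were Cd79b, a signalling chain of the B cell receptor that fell from 33.9 and 39.2 CPM to 14.1 and 10.2 CPM, Cd22, Ighm and Ighd. The calls of Igkc, Iglc2, Cd22, Ighm and Ighd ended without WT replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.330, 0.213, 0.161, 0.127 and 0.0690), and the log2 differences of Igkc and Iglc2 were 0.30 and 1.59 without P65KO-labelled replicate 1 and did not pass. With DESeq2 the calls of Igkc, Iglc2, Ighm and Ighd ended (Benjamini-Hochberg adjusted p of 0.350, 0.0730, 0.121 and 0.0755), and with robust estimation those of Igkc, Iglc2 and Ighm (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.432, 0.344 and 0.162). No filter ended the calls of all 5, limma-voom those of Igkc and Iglc2, and leaving out WT replicate 2 those of all but Ighd. All 4 tested members of the erythroid and platelet list rose, also adjusted over the list alone. They were Hba-a1, Hba-a2, Hbb-bs and Alas2, all erythroid, and no platelet marker was tested. The list median was 2.51 (camera, Benjamini-Hochberg adjusted p = 1.63e-07), a call lost at adjusted p = 0.259 with an estimated correlation. The haemoglobin genes Hba-a1 and Hba-a2 were 6.55-fold and 7.74-fold higher, Hba-a1 at 37.0 and 59.6 CPM in P65KO-labelled replicates 1 and 2. The call of Hbb-bs ended with no filter, with robust estimation and without WT replicate 1 or WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.101, 0.207, 0.101 and 0.0662), and its log2 difference of 2.30 was 1.47 without P65KO-labelled replicate 2. That of Alas2 ended without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0534).

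CD8 T cell markers had 0 of 5 genes past the threshold with edgeR, DESeq2 and limma-voom, with 4 at an unadjusted edgeR p under 0.05, and 2 higher and 1 lower adjusted over the list alone (median 0.33; camera, Benjamini-Hochberg adjusted p = 0.544). Klrd1 passed with robust estimation, with either replicate block and without P65KO-labelled replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0203 to 0.0463). NK and innate lymphoid markers had 1 of 7 higher (Prf1), 1 lower (Klrb1c, 4.36-fold) and 5 that did not pass, with the same numbers adjusted over the list alone (median 0.30; camera, Benjamini-Hochberg adjusted p = 0.732). The gamma-delta T cell list had 1 tested gene, Trdc, which was 1.90-fold higher, and the stromal and endothelial list 1, Pecam1 (CD31), which rose from 157 to 236 CPM. The calls of Trdc, Pecam1 and Prf1 ended without WT replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.101, 0.0637 and 0.0951). Those of Trdc and Prf1 also ended with DESeq2 (Benjamini-Hochberg adjusted p of 0.0953 and 0.202) and without WT replicate 1, those of Pecam1 and Prf1 with no filter, and that of Prf1 without P65KO-labelled replicate 1. Neither list was large enough for the list test.

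**Figure D3:**
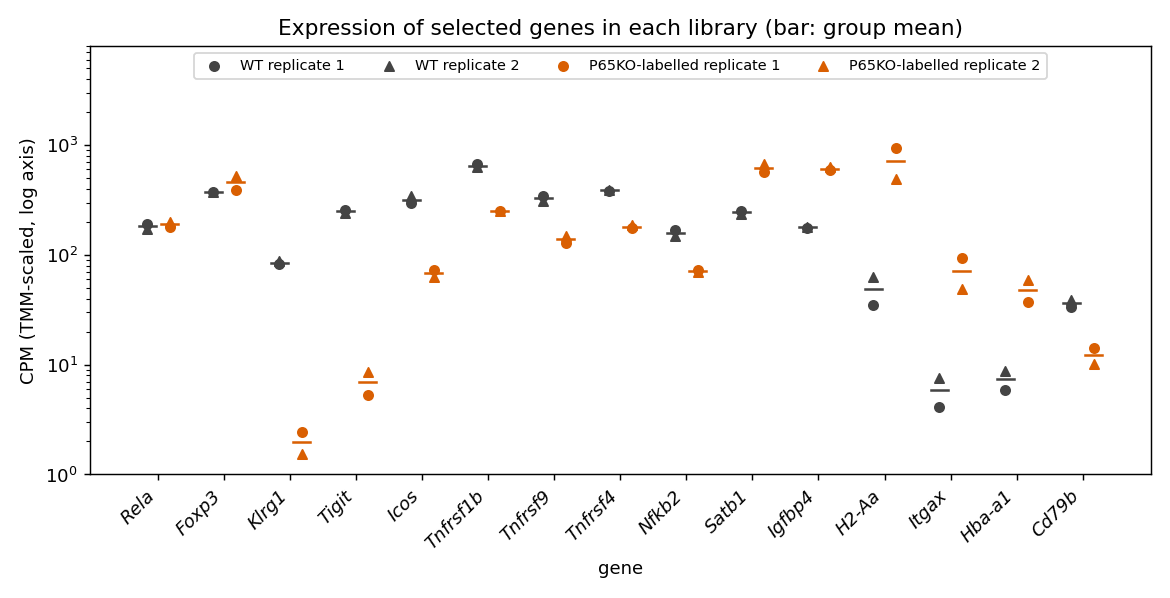
CPM scaled by TMM (vertical log axis) of 15 genes (horizontal axis) in each library, WT in grey and P65KO-labelled in orange, with circles for replicate 1, triangles for replicate 2 and bars at group means. Rela overlaps between the groups, Tigit and Klrg1 lie lower in both P65KO-labelled libraries, and H2-Aa and Itgax lie higher, most in replicate 1 (934 and 94.2 CPM).

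Camera called 17 of the 25 tested lists with the preset correlation, 10 lower and 7 higher. With an estimated correlation it called 0 after adjustment and 7 at an unadjusted p under 0.05, with an adjusted p of 0.104 to 0.597 for the 17. Fry called 10. For the NF-kB target, trafficking and cholesterol lists the estimated correlation was -0.009, -0.025 and -0.015, below the preset 0.01. Genes varying together therefore do not account for the loss of those calls, and that setting had little power with 4 libraries. With fry, the lists of effector, naive, NF-kB target, NF-kB family, TNF receptor, TNF ligand, T helper, trafficking, cholesterol and sex-linked genes passed, and fry compares none of them with other genes.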

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

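Leaving out X and Y genes, removing the gene length trend and crossing the block were chosen after the data were seen, and the other alternatives were planned. The 2310 changed genes became 771 with no filter on low counts (246 higher, 525 lower, or 68.1% lower against 56.5%) and 1318 with DESeq2 (587 higher, 731 lower), and the cause was not tested. Leaving out each library in turn gave 916 to 1676 changed genes, 331 to 680 higher and 585 to 1053 lower, with fewer samples and a lone library assumed to vary like the other group. The count was 919 without WT replicate 1 and 916 without WT replicate 2, and with P65KO-labelled replicate 1 left out 623 genes were higher. RLE and upper-quartile scaling, the stricter filter, limma-voom and robust estimation gave 2137 to 2400, and the 2230 genes without X and Y and the 2514 without the length trend shared 2225 and 2298 genes with the main call. No gene called in the main comparison and in an alternative had the opposite sign in any setting run.

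The Rela difference ran from -0.01 to 0.15 over the libraries left out in turn, and changed sign without P65KO-labelled replicate 2 (-0.0066). Fcgr3, an Fc receptor gene that did not pass in the main comparison, ran from -0.54 to 2.64, the lowest without P65KO-labelled replicate 1. Of 1805 results for single genes named by the rule other than Rela, 1684 kept direction and side of the threshold, 108 fell below it, 12 passed it and 1 changed sign. Among these, robust estimation lost 8 calls and no filter 27. Of 522 for genes named after their values were seen, 436 stayed and 86 fell below. Camera called 17 lists, 0 with an estimated correlation, and fry 10. The NK list changed direction with the stricter filter (camera adjusted p = 0.932) and without WT replicate 1 or P65KO-labelled replicate 1, and ran from 0.221 to 0.872 over the libraries left out. The oxidative phosphorylation list changed direction without the same libraries and ran from 0.151 to 0.962. Neither list was called in any of these.

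The replicate numbers are not said to pair the mice, and same-numbered libraries deviated with a correlation of -0.137 across genes. With the replicate block 2319 genes changed, 2162 of them shared with the main call, and among named genes it ended the calls of Tap1, Tapbp and Klf6 and added Klrd1, Fcgr3 and Uqcrfs1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.0315, 0.00421 and 0.0308). With the crossed replicate block 2973 genes changed. In simulations 56.7% of genes changed 1.5-fold and 95.5% of those changed 4-fold were called. A comparison on counts of the single-library files was not run, because those files hold log2 RPKM of the same counts.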

Other observations

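The tests of explanations in this part were chosen after the results were seen, and the genes of the next paragraph were picked after their values were seen.

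Among genes outside the lists, several regulators and receptors moved strongly with the genotype label. Tox2, an HMG-box factor of follicular helper cells, fell 18.2-fold, and Nav2, a neuron navigator gene, fell from 62.3 to 3.64 CPM. Axl, a receptor tyrosine kinase, fell 6.24-fold, Angptl2, a secreted angiopoietin-like protein, 6.65-fold, Bhlhe40, a transcription factor of activated T cells, 5.64-fold, and Ptger2, a prostaglandin E2 receptor, 5.18-fold. From the lists, Il10, the suppressive cytokine, had 41 counts in WT and 1 in P65KO-labelled libraries, a ratio of 40.1 (exact 95% interval 6.80 to 1622). The fitted log2 difference of Il10, -5.02, was -4.16 without P65KO-labelled replicate 1 and -7.36 without P65KO-labelled replicate 2. Higher in P65KO-labelled libraries were Myo6, an unconventional myosin, 8.01-fold, Cnn3, an actin-binding calponin, 3.09-fold, the semaphorin gene Sema4a, 2.71-fold, and, from the trafficking list, the integrin gene Itgb3, 2.06-fold. Wdfy4 and Sirpa, both expressed by dendritic cells, were 11.9-fold and 7.86-fold higher, Wdfy4 by log2 4.29 without WT replicate 2. Cebpa, a transcription factor gene of myeloid cells, went the other way, from 40.9 ± 6.05 CPM in WT to 10.2 ± 9.66 CPM (SD, n = 2 each). Within 5 Mb of Rela, 22 of 165 tested genes changed, 11 higher and 11 lower, or 13.3% against 20.9% on other chromosomes (two-sided Fisher's exact test, p = 0.0156, genes not being independent).

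Rela was not lower in libraries labelled as lacking it. Loss of the whole transcript from most cells was excluded, since the lower 95% bound of the log2 difference was -0.139 where a halving would be -1. The libraries grouped as labelled, with a lowest correlation within a group of 0.982 and a highest between groups of 0.936. This cannot exclude a wrong genotype label on a single library, since libraries of a group also shared sex-linked and myeloid transcript levels. Deletion of some exons with the rest still counted may account for the Rela counts. There were 0 columns with counts per exon, so a deletion of some exons cannot be told apart from an intact gene. An exchange of the labels of both groups was not tested. Of 38 NF-kB target genes, 25 were lower and 3 higher in the P65KO-labelled libraries, the direction that loss of RelA there would give. That list shares 32 members with other lists, and 45 of 49 effector markers fell too, so this direction cannot decide whether the labels are right.

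Effector genes were lower and naive genes higher, which may reflect the genotype or another difference between the mice. Dilution by Foxp3-negative CD4 T cells as the whole source of the effector fall was argued against. The lower 95% bound of Foxp3 was 0.0155 on the log2 scale, while the effector median was -1.70. A partial dilution was not tested, nor was the premise that Foxp3 expression per Treg cell was alike in both groups. Foxp3 stood at 377 and 371 CPM in WT and at 386 and 528 CPM in P65KO-labelled replicates 1 and 2. Of 25 core Treg identity genes, 13 fell and 5 rose. Myeloid cells among the sorted cells were argued against as the source of the naive rise, because the median log2 ratio of P65KO-labelled replicate 1 to replicate 2 was -0.0556 over the naive list and 1.12 over the called myeloid genes. The sex of the mice stays open, because 0 groups held libraries of both sexes, and sex and genotype label cannot be told apart for these lists. A lower share of effector cells among Treg cells and a lower expression per cell both remain untested.

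Myeloid, dendritic and MHC class II genes were higher in P65KO-labelled libraries, although the cells are described as CD4+Foxp3+, a gate that should remove such cells. Cd79b-expressing B cells as the source were excluded, since the B cell list without MHC class II genes had a median log2 difference of -0.767 (SD 2.20 over 7 genes) against 3.70 for those genes, and Cd79b fell by -1.59. Its immunoglobulin members Iglc2 and Igkc rose, by 3.67 and 1.41 (1.59 to 4.72 and 0.30 to 2.04 over the libraries left out in turn, lowest without P65KO-labelled replicate 1), so antibody-secreting cells were not excluded. Dendritic or other myeloid cells among the sorted cells are a candidate source, although the myeloid gene Cebpa fell 4.01-fold. Of the 11 called myeloid genes, Lyz2 (635 and 193 CPM) among them, 100% had more CPM in P65KO-labelled replicate 1 than in replicate 2. H2-Aa had the same order (934 and 487 CPM), which was known when this test was chosen. The haemoglobin genes had the opposite order of replicates (Hba-a1 37.0 and 59.6 CPM), so a single source for both sets is not indicated by these values.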
